A study of Homo sapiens with 24 samples.

How the data were processed

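RNA sequencing data of 24 libraries from the human lines PANC-1 and HEK293T were analysed, in 8 groups of 3 libraries: each line in 2D culture, in AggreWell microwells, and in dual-axis rotating capillary containers (DRCC) at 1 rpm and at 30 rpm. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted with TRIzol, its amount and quality were measured, and libraries were made with a VAHTS Universal V10 RNA-seq kit. Whether the kit's protocol selected poly(A) RNA or marked strand is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner could not be told apart. The authors deposited 1 table of FPKM values for 26450 genes (fragments per kilobase of transcript, scaled to the depth of each library). Per the submitters' processing notes, fastp, HISAT2, HTSeq and R 3.2.0 were used, in roles that the notes do not give. The notes also name the mouse build mm10, while the table holds human gene symbols, of which 25154 were found among human RefSeq symbols and synonyms. No coordinates were used.

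Depth was recovered from the values. Within tolerance of 0.01, every value of 26449 genes was a whole multiple of the value of 1 fragment, and 1 gene was not. The recovered totals ran from 32021638 to 39556154 fragments per library. FPKM relates each gene to the total of its own library, so a change in a few abundant genes shifts all others.

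Tests were run on log2(FPKM + 1), with a pseudocount of 1, using limma 3.58.1 in R 4.3.3 with an intensity trend on the variance. Tables and figures were prepared in Python 3.11.15 with pandas 2.3.3. Genes with an FPKM of at least 1 in at least 3 libraries were kept: 11585 in PANC-1, 12548 in HEK293T and 13392 where both lines were fitted together. Each line was fitted over its 12 libraries, with the 6 comparisons between formats as contrasts, and the difference between the lines was tested as an interaction over all 24 libraries. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Those changed by at least 2-fold were counted beside them. Gene lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation. The members counted are those that passed the FPKM filter. Lists can share members, as SLC7A11 is in both the amino acid stress and the NRF2 oxidative stress list. Results of such lists are not independent of each other. A list said to hold with an estimated correlation is one whose second adjusted p was also under 0.05.

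The gene lists, the tests of each comparison, the rule for naming genes and the alternatives below were fixed before the data were examined. Voom on the recovered fragments, the removal of a trend in GC content and transcript length, the tests of technical explanations, the set of histone genes and the counts of changes shared by the lines were added later. The rule named, per line and comparison, the 6 genes with the largest rise and the 6 with the largest fall among called protein-coding genes. These needed a mean FPKM of at least 5 in the higher format and no overlap between the 3 libraries of each format, which chance gives for 10% of genes. It further named the 4 called members of each list with the largest absolute change, or the 2 most expressed if none was called. For the line difference it named 6 genes called in opposite directions in the lines. The text takes the first ones of each, and some genes that the rule names are not reported here. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, mitochondrially encoded genes left out, each comparison fitted on its own 2 formats, robust variance shrinkage, the replicate number as a block, and each library left out in turn. Where mitochondrially encoded genes were left out, the remaining FPKM values of each library were also scaled to a common total. Shifts under that setting therefore cannot be credited to those genes alone.

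The procedure was tested on simulated values with known changes and independent normal noise of each gene's own spread. Changes were given only to genes with a 2D level of at least 5 FPKM, and all others were left unchanged. In the real data most genes were called, so recovery and false calls need not be the same there or for weaker genes. For AggreWell against 2D in PANC-1, 100 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold were recovered among 11585 genes, with 9 false calls. In HEK293T the numbers were 99 and 100 among 12548 genes, with 11 false calls, and for the line difference 100 and 100 among 13392, with 10. Genes with near-identical copies (HSPA1A and HSPA1B, histone genes, BOLA2B, SMIM11 and mitochondrially encoded genes) are uncertain, since the counting may have divided or dropped their reads. Other groupings of the libraries were drawn for each comparison, all 10 within a line and 100 of the 200 for the line difference, the latter redrawn without repeats after a first draw with repeats had been seen.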

Results

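RNA was sequenced from 24 libraries of 2 human cell lines. PANC-1 is an epithelial line from a pancreatic duct carcinoma, and HEK293T is a transformed embryonic kidney line. Each line was grown in 4 formats with 3 libraries per format: flat culture (2D), microwell aggregates (AggreWell), and spheroids in dual-axis rotating capillary containers (DRCC) turned at 1 rpm or at 30 rpm. The comparisons ask how transcript levels differed between these formats within a line, and whether that difference was shared by the lines. Libraries held between 32021638 and 39556154 fragments. DRCC libraries were shallower than those of 2D, with 34018135 to 36656956 fragments at 1 rpm and 36492538 to 36890881 at 30 rpm against 38061349 to 39556154 in PANC-1. In HEK293T the ranges were 35020379 to 35675959, 32021638 to 32557265 and 38778091 to 39345190 in the same order. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

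Levels are given as mean FPKM ± SD over 3 libraries, first in the format compared against and then in the format of interest. They are followed by the log2 fold change ± SE (n = 3 per format), which is on the log2(FPKM + 1) scale and so understates the change of low genes. A lone value with its error after a gene is that log2 fold change. Genes were named by a fixed rule that ranks well-expressed protein-coding genes, and the members of each gene list, by fold change, so that words such as first and largest refer to that ranking. The median of all tested genes was not at 0: against 2D it stood at 0.098, 0.15 and 0.17 on the log2 scale for AggreWell, 1 rpm and 30 rpm in PANC-1, and at 0.12, 0.18 and 0.13 in the same order in HEK293T. Fold changes are to be read against those shifts, and camera tests each list against the other genes.

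Libraries of one format resembled each other closely, and the DRCC libraries stood farthest from 2D in both lines. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.998 among PANC-1 2D libraries and 0.983 to 0.985 between 2D and AggreWell. They were 0.93 to 0.932 between 2D and DRCC at 30 rpm, and 0.98 to 0.981 between the rotation speeds. In HEK293T the corresponding ranges were 0.997 to 0.998, 0.969 to 0.973, 0.925 to 0.932 and 0.989 to 0.99. Line markers matched the labels. The mean log2 level of PANC-1 markers less that of HEK293T markers lay between 3.91 and 4.20 in PANC-1 libraries and between -1.78 and -1.62 in HEK293T libraries.

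**Figure D1:**
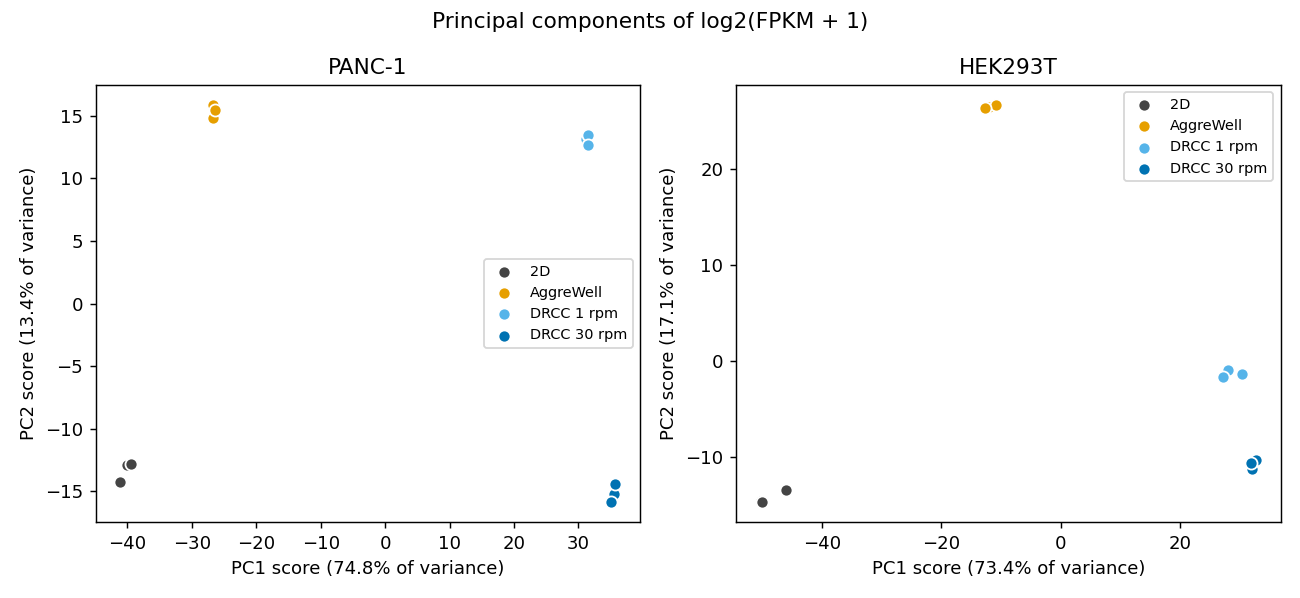
Scores of the libraries on principal components 1 and 2 of log2(FPKM + 1), PANC-1 on the left and HEK293T on the right, 1 point per library and 1 colour per culture format. Component 1, with 74.8% and 73.4% of the variance, runs from 2D through AggreWell to the DRCC libraries.

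PANC-1 cells in AggreWell, compared with 2D, expressed more LXN (14.3 ± 1.15 to 69.5 ± 1.07 FPKM, log2 2.21 ± 0.05), a carboxypeptidase inhibitor, and MEGF6 (0.858 ± 0.0364 to 5.25 ± 0.0876 FPKM, log2 1.75 ± 0.05). They expressed less TGM2 (10.8 ± 1.07 to 2.26 ± 0.0783 FPKM, log2 -1.86 ± 0.08), a transglutaminase, and CCN2 (74.7 ± 3.04 to 20.6 ± 0.268 FPKM, log2 -1.81 ± 0.04), a secreted matricellular protein. YAP/TAZ targets, whose transcription follows cell shape and contact, were lower: 2 rose and 15 fell of 20 tested, and the median log2 change was -0.49 (camera adjusted p = 9.7e-09; adjusted p = 0.022 with an estimated correlation). After CCN2, the largest falls in this list were those of CCN1 (-1.57 ± 0.03), ANKRD1 (-1.22 ± 0.07) and AMOTL2 (-1.10 ± 0.04). Of 21 cholesterol synthesis genes tested, 0 rose and 17 fell, with a median log2 change of -0.37 (camera adjusted p = 9.7e-09; adjusted p = 0.025 with an estimated correlation). INSIG1 (-0.96 ± 0.05) fell most. Of 18 hypoxia response genes tested, 14 rose and 2 fell, with a median log2 change of 0.52 (camera adjusted p = 0.0040; adjusted p = 0.038 with an estimated correlation). NDRG1 (1.48 ± 0.03), PFKFB4 (1.36 ± 0.06) and DDIT4 (1.25 ± 0.04) had the largest rises. Of 23 ATF4 amino acid stress genes tested, 3 rose and 15 fell, with a median log2 change of -0.26 (camera adjusted p = 3.9e-05; adjusted p = 0.022 with an estimated correlation). That median was -0.17 with mitochondrially encoded genes left out. CEBPB (-0.65 ± 0.03) and ATF4 (-0.62 ± 0.03) itself fell most. The unfolded protein response went the same way: 4 rose and 10 fell of 17 tested, and the median log2 change was -0.21 (camera adjusted p = 0.0017; adjusted p = 0.034 with an estimated correlation). That median was -0.35 with median-ratio scaling and -0.11 with mitochondrially encoded genes left out. This list was headed by SDF2L1 (-0.69 ± 0.07) and XBP1 (-0.64 ± 0.04). The largest limma adjusted p among the genes named here was 2.1e-06. In limma, 8110 of 11585 genes passed, 5322 higher and 2788 lower, of which 141 were at least 2-fold higher and 26 at least 2-fold lower. Camera called 14 of 27 gene lists, 6 of them with an estimated correlation, and the counts above were the same adjusted over the list alone, except cholesterol synthesis with 0 and 18. Median-ratio scaling gave 3837 higher and 4300 lower (88 and 43 at least 2-fold), and quantile normalization gave 3472 higher and 4063 lower (69 and 32 at least 2-fold). Leaving out mitochondrially encoded genes, which also scaled libraries to a common FPKM total, gave 6676 higher and 1823 lower (207 and 19 at least 2-fold). Mitochondrially encoded genes took 4.28 ± 0.03% of fragments, against 4.33 ± 0.31% in 2D, so their share hardly differed. Removing the GC and length trend gave 5181 higher and 2519 lower (84 and 21 at least 2-fold).

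At 1 rpm in the DRCC, PANC-1 cells had more NR4A2 (0.576 ± 0.142 to 69.9 ± 1.88 FPKM, log2 5.50 ± 0.05), an immediate early nuclear receptor, than in 2D. PER1 (3.84 ± 0.394 to 144 ± 4.66 FPKM, log2 4.91 ± 0.05), a circadian clock gene, and NGFR (1.31 ± 0.172 to 37.4 ± 1.51 FPKM, log2 4.06 ± 0.05), a neurotrophin receptor, were also higher. Lower genes were DKK1 (143 ± 5.38 to 9.57 ± 0.683 FPKM, log2 -3.77 ± 0.05), a secreted Wnt inhibitor, CCN2 (74.7 ± 3.04 to 7.96 ± 0.324 FPKM, log2 -3.08 ± 0.04), and FEN1 (72.8 ± 1.49 to 10.4 ± 0.953 FPKM, log2 -2.70 ± 0.06), a flap endonuclease of DNA replication. DNA replication genes fell as a group: 0 rose and 25 fell of 25 tested, and the median log2 change was -1.61 (camera adjusted p = 3.0e-13; adjusted p = 0.0026 with an estimated correlation). After FEN1 came MCM4 (-2.01 ± 0.03), GINS1 (-2.00 ± 0.06) and CDC6 (-2.00 ± 0.05). Of 25 mitosis genes tested, 7 rose and 17 fell, with a median log2 change of -0.67 (camera adjusted p = 7.1e-04; adjusted p = 0.18 with an estimated correlation). BIRC5 (-1.31 ± 0.03) and AURKA (-1.23 ± 0.03) led them. Of 18 immediate early and flow-responsive genes tested, 15 rose and 2 fell, with a median log2 change of 1.78 (camera adjusted p = 7.1e-04; adjusted p = 0.10 with an estimated correlation). ZFP36 (3.86 ± 0.05), EGR1 (3.39 ± 0.05) and NR4A1 (3.16 ± 0.04) were first. Of 16 heat shock genes tested, 0 rose and 14 fell, with a median log2 change of -0.54 (camera adjusted p = 3.9e-05; adjusted p = 0.014 with an estimated correlation). The co-chaperones STIP1 (-1.22 ± 0.03) and DNAJA1 (-0.96 ± 0.02) fell most. Mitochondrially encoded genes were lower: 1 rose and 11 fell of 13 tested, and the median log2 change was -1.75 (camera adjusted p = 4.1e-05; adjusted p = 0.28 with an estimated correlation). These transcripts took 2.37 ± 0.0716% of fragments, against 4.33 ± 0.31% in 2D. Among the genes named here the largest limma adjusted p was 1.3e-12. In limma, 9985 of 11585 genes passed, 6063 higher and 3922 lower, of which 1214 were at least 2-fold higher and 431 at least 2-fold lower. Camera called 10 of 27 gene lists, 2 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 4936 higher and 4942 lower (893 and 685 at least 2-fold), and quantile normalization gave 4807 higher and 5053 lower (698 and 630 at least 2-fold).

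With rotation at 30 rpm, PANC-1 cells had more NGFR (1.31 ± 0.172 to 140.3 ± 1.66 FPKM, log2 5.94 ± 0.05), NR4A2 (0.576 ± 0.142 to 63.3 ± 1.25 FPKM, log2 5.35 ± 0.05) and the histone gene H2BC21 (0.774 ± 0.231 to 51.7 ± 0.156 FPKM, log2 4.90 ± 0.07) than in 2D. The mitochondrial complex I gene ND6 (613 ± 81.5 to 2.42 ± 0.381 FPKM, log2 -7.48 ± 0.09) had the largest fall. It was followed by DKK1 (143 ± 5.38 to 12.3 ± 0.861 FPKM, log2 -3.44 ± 0.05) and COX3 (4234 ± 281 to 393 ± 13.8 FPKM, log2 -3.42 ± 0.04). DNA replication genes were lower: 0 rose and 25 fell of 25 tested, and the median log2 change was -1.34 (camera adjusted p = 2.1e-13; adjusted p = 0.0025 with an estimated correlation). Of 25 mitosis genes tested, 3 rose and 20 fell, with a median log2 change of -0.72 (camera adjusted p = 8.1e-08; adjusted p = 0.0490 with an estimated correlation). AURKA (-1.79 ± 0.03), CCNB1 (-1.56 ± 0.02) and MKI67 (-1.39 ± 0.05) led them. The amino acid stress response rose: 17 rose and 2 fell of 23 tested, and the median log2 change was 1.03 (camera adjusted p = 0.0055; adjusted p = 0.0490 with an estimated correlation). DDIT3 (3.19 ± 0.05), ATF3 (2.61 ± 0.05) and SLC7A11 (2.23 ± 0.07) had the largest rises. Of 18 immediate early and flow-responsive genes tested, 16 rose and 2 fell, with a median log2 change of 1.82 (camera adjusted p = 3.8e-05; adjusted p = 0.0490 with an estimated correlation). ZFP36 (4.23 ± 0.05) and FOS (3.97 ± 0.05) were first. Of 20 YAP/TAZ targets tested, 3 rose and 15 fell, with a median log2 change of -0.59 (camera adjusted p = 2.7e-05; adjusted p = 0.0490 with an estimated correlation). ANKRD1 (-2.32 ± 0.07) and CCN2 (-1.91 ± 0.04) fell most, while GADD45A (1.46 ± 0.04), a DNA damage gene, rose. Of 17 NRF2 oxidative stress genes tested, 13 rose and 2 fell, with a median log2 change of 0.77 (camera adjusted p = 0.018; adjusted p = 0.074 with an estimated correlation). HMOX1 (4.36 ± 0.06), which encodes a haem-degrading oxygenase, led. Mitochondrially encoded genes fell: 0 rose and 13 fell of 13 tested, and the median log2 change was -2.37 (camera adjusted p = 4.4e-08; adjusted p = 0.13 with an estimated correlation). These genes took 1.60 ± 0.0269% of fragments. No named gene here had a limma adjusted p above 6.1e-12. In limma, 9935 of 11585 genes passed, 6209 higher and 3726 lower, of which 1264 were at least 2-fold higher and 378 at least 2-fold lower. Camera called 15 of 27 gene lists, 6 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 5005 higher and 4929 lower (888 and 613 at least 2-fold), and quantile normalization gave 4677 higher and 5096 lower (687 and 590 at least 2-fold). Histone and mitochondrially encoded genes have close copies elsewhere in the genome, so their levels are uncertain.

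Set against AggreWell, DRCC at 1 rpm had higher NR4A2 (0.935 ± 0.0731 to 69.9 ± 1.88 FPKM, log2 5.20 ± 0.05), PER1 (3.69 ± 0.0814 to 144 ± 4.66 FPKM, log2 4.95 ± 0.05) and the clock repressor NR1D1 (3.63 ± 0.346 to 63.5 ± 2.00 FPKM, log2 3.80 ± 0.07) in PANC-1. DKK1 (142 ± 2.51 to 9.57 ± 0.683 FPKM, log2 -3.76 ± 0.05), ID2 (55.9 ± 0.802 to 3.74 ± 0.258 FPKM, log2 -3.58 ± 0.08), an inhibitor of DNA binding, and FAM111B (16.7 ± 0.617 to 1.41 ± 0.0451 FPKM, log2 -2.88 ± 0.05) were lower. DNA replication genes were lower in the DRCC: 0 rose and 25 fell of 25 tested, and the median log2 change was -1.45 (camera adjusted p = 1.9e-12; adjusted p = 0.0032 with an estimated correlation). Mitosis genes followed: 0 rose and 25 fell of 25 tested, and the median log2 change was -0.76 (camera adjusted p = 1.7e-10; adjusted p = 0.016 with an estimated correlation). FEN1 (-2.45 ± 0.06), MCM4 (-1.88 ± 0.03), HMMR (-1.45 ± 0.04) and MKI67 (-1.39 ± 0.05) led these lists. Of 14 NF-kB and inflammatory cytokine genes tested, 12 rose and 1 fell, with a median log2 change of 1.35 (camera adjusted p = 2.0e-04; adjusted p = 0.016 with an estimated correlation). NFKBIA (2.07 ± 0.04), ICAM1 (1.81 ± 0.04) and CXCL3 (1.76 ± 0.13) were first. Of 21 cholesterol synthesis genes tested, 16 rose and 4 fell, with a median log2 change of 0.81 (camera adjusted p = 5.8e-04; adjusted p = 0.086 with an estimated correlation). MSMO1 (2.20 ± 0.04) and HMGCS1 (2.07 ± 0.04) moved most. Of 20 glycolysis genes tested, 1 rose and 16 fell, with a median log2 change of -0.34 (camera adjusted p = 6.2e-05; adjusted p = 0.014 with an estimated correlation). The glucose transporter gene SLC2A3 (1.82 ± 0.08) rose while ENO2 (-1.30 ± 0.05) and LDHA (-1.18 ± 0.02) fell. Amino acid stress genes were higher: 17 rose and 4 fell of 23 tested, and the median log2 change was 0.86 (camera adjusted p = 0.0013; adjusted p = 0.022 with an estimated correlation). DDIT3 (2.73 ± 0.05) and ATF3 (1.76 ± 0.05) headed them. Over the genes named here, limma adjusted p reached at most 2.0e-08. In limma, 9504 of 11585 genes passed, 5058 higher and 4446 lower, of which 599 were at least 2-fold higher and 351 at least 2-fold lower. Camera called 16 of 27 gene lists, 7 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 4725 higher and 4782 lower (545 and 396 at least 2-fold), and quantile normalization gave 4649 higher and 4871 lower (523 and 456 at least 2-fold). A minimum mean FPKM of 5 gave 3117 higher and 3177 lower (356 and 239 at least 2-fold).

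DRCC at 30 rpm, compared with AggreWell in PANC-1, had higher NGFR (1.75 ± 0.144 to 140.3 ± 1.66 FPKM, log2 5.68 ± 0.05), NR4A2 (0.935 ± 0.0731 to 63.3 ± 1.25 FPKM, log2 5.05 ± 0.05) and HMOX1 (9.46 ± 0.518 to 236 ± 0.88 FPKM, log2 4.50 ± 0.06). ND6 (790.0 ± 15.3 to 2.42 ± 0.381 FPKM, log2 -7.86 ± 0.09), DKK1 (142 ± 2.51 to 12.3 ± 0.861 FPKM, log2 -3.43 ± 0.05) and COX3 (3911 ± 31.4 to 393 ± 13.8 FPKM, log2 -3.31 ± 0.04) were lower. Unfolded protein response genes rose: 16 rose and 0 fell of 17 tested, and the median log2 change was 0.69 (camera adjusted p = 2.5e-05; adjusted p = 0.011 with an estimated correlation). The first were HERPUD1 (2.35 ± 0.05), DNAJB9 (1.90 ± 0.08) and the chaperone gene HSPA5 (1.89 ± 0.02). Of 23 amino acid stress genes tested, 20 rose and 2 fell, with a median log2 change of 1.24 (camera adjusted p = 1.1e-05; adjusted p = 0.011 with an estimated correlation). DDIT3 (3.49 ± 0.05) and ATF3 (2.97 ± 0.05) rose most. Of 17 NRF2 oxidative stress genes tested, 15 rose and 1 fell, with a median log2 change of 0.64 (camera adjusted p = 1.8e-04; adjusted p = 0.011 with an estimated correlation). HMOX1 was followed by SLC7A11 (2.14 ± 0.07) and GCLM (1.21 ± 0.05). DNA replication genes fell: 0 rose and 24 fell of 25 tested, and the median log2 change was -1.22 (camera adjusted p = 2.2e-11; adjusted p = 0.0044 with an estimated correlation). Of 25 mitosis genes tested, 0 rose and 24 fell, with a median log2 change of -0.98 (camera adjusted p = 2.2e-11; adjusted p = 0.011 with an estimated correlation). FEN1 (-2.72 ± 0.06) led the former and MKI67 (-1.93 ± 0.05) and HMMR (-1.89 ± 0.04) the latter. The highest limma adjusted p of these named genes was 9.1e-11. In limma, 9648 of 11585 genes passed, 5264 higher and 4384 lower, of which 770 were at least 2-fold higher and 382 at least 2-fold lower. Camera called 11 of 27 gene lists, 6 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 4814 higher and 4863 lower (677 and 449 at least 2-fold), and quantile normalization gave 4615 higher and 5151 lower (648 and 501 at least 2-fold). Leaving out mitochondrially encoded genes gave 4336 higher and 5357 lower (583 and 519 at least 2-fold).

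The faster rotation had more of the replication-dependent histone genes H2AC8 (2.45 ± 0.597 to 19.0 ± 1.49 FPKM, log2 2.55 ± 0.16) and H2BC17 (1.55 ± 0.183 to 13.3 ± 0.721 FPKM, log2 2.49 ± 0.19) than the slower one in PANC-1. BOLA2B (2.20 ± 0.81) came next, with a limma adjusted p of 0.028, but its libraries at 30 rpm read 69.5, 2.12 and 3.13 FPKM and it has a near-identical copy. Without the first of these libraries its log2 fold change was 0.77 (limma adjusted p = 0.0044), and without replicate 1 or 2 at 1 rpm it was 2.17 (limma adjusted p = 0.061) or 2.12 (limma adjusted p = 0.065). ND6 (119 ± 6.46 to 2.42 ± 0.381 FPKM, log2 -5.13 ± 0.09), C15orf48 (-1.51 ± 0.10) and IRF1 (-1.44 ± 0.05), an interferon-regulated transcription factor, were lower at 30 rpm. NF-kB and inflammatory cytokine genes fell: 2 rose and 10 fell of 14 tested, and the median log2 change was -1.09 (camera adjusted p = 1.3e-04; adjusted p = 0.015 with an estimated correlation). NFKBIA (-1.42 ± 0.04), TNFAIP2 (-1.39 ± 0.04) and CXCL2 (-1.33 ± 0.08) fell most. Of 23 amino acid stress genes tested, 19 rose and 1 fell, with a median log2 change of 0.43 (camera adjusted p = 4.4e-06; adjusted p = 0.011 with an estimated correlation). PSAT1 (1.22 ± 0.03) and ATF3 (1.21 ± 0.05) headed them. Of 17 unfolded protein response genes tested, 15 rose and 0 fell, with a median log2 change of 0.42 (camera adjusted p = 9.2e-06; adjusted p = 0.011 with an estimated correlation). SDF2L1 (1.12 ± 0.07) and HERPUD1 (0.97 ± 0.05) were first. Of 17 NRF2 oxidative stress genes tested, 13 rose and 0 fell, with a median log2 change of 0.43 (camera adjusted p = 4.7e-05; adjusted p = 0.012 with an estimated correlation). HMOX1 (1.45 ± 0.06) led. BOLA2B aside, limma adjusted p was at most 1.2e-07 among the genes named here. In limma, 7885 of 11585 genes passed, 4188 higher and 3697 lower, of which 88 were at least 2-fold higher and 37 at least 2-fold lower. Camera called 12 of 27 gene lists, 4 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Quantile normalization gave 3762 higher and 4237 lower (92 and 39 at least 2-fold), and leaving out mitochondrially encoded genes gave 2943 higher and 5063 lower (70 and 47 at least 2-fold). Removing the GC and length trend gave 3944 higher and 3202 lower (44 and 41 at least 2-fold).

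In HEK293T, AggreWell had more TCEAL7 (0.669 ± 0.086 to 20.2 ± 1.05 FPKM, log2 3.67 ± 0.07), PLOD2 (16.5 ± 1.73 to 101 ± 3.39 FPKM, log2 2.54 ± 0.06), a collagen lysyl hydroxylase, and HSP90AA1 (121 ± 0.334 to 630.2 ± 5.06 FPKM, log2 2.37 ± 0.02) than 2D. The largest falls were those of HSPA1A (33.0 ± 4.89 to 9.69 ± 1.31 FPKM, log2 -1.67 ± 0.15), ND6 (234 ± 18.2 to 79.6 ± 8.27 FPKM, log2 -1.54 ± 0.08) and ND2 (2736 ± 117 to 1073 ± 56.3 FPKM, log2 -1.35 ± 0.04). Hypoxia response genes rose together: 19 rose and 0 fell of 19 tested, and the median log2 change was 1.5 (camera adjusted p = 1.3e-08; adjusted p = 0.0045 with an estimated correlation). The first were P4HA1 (2.34 ± 0.04), NDRG1 (2.26 ± 0.03), LOX (1.97 ± 0.07) and BNIP3L (1.92 ± 0.05). Of 19 glycolysis genes tested, 16 rose and 2 fell, with a median log2 change of 0.49 (camera adjusted p = 2.7e-04; adjusted p = 0.24 with an estimated correlation). ENO2 (2.12 ± 0.05), ALDOC (1.69 ± 0.04) and SLC2A3 (1.60 ± 0.04) rose most. Mitochondrially encoded genes fell: 0 rose and 13 fell of 13 tested, and the median log2 change was -0.95 (camera adjusted p = 1.7e-08; adjusted p = 0.028 with an estimated correlation). That median was -0.55 with quantile normalization. These genes took 3.51 ± 0.0693% of fragments, against 4.77 ± 0.0849% in 2D. Of 17 NRF2 oxidative stress genes tested, 2 rose and 13 fell, with a median log2 change of -0.28 (camera adjusted p = 2.7e-04; adjusted p = 0.028 with an estimated correlation). That median was -0.43 with median-ratio scaling and -0.15 with mitochondrially encoded genes left out. TALDO1 (-0.69 ± 0.03) was lower and OSGIN1 (0.63 ± 0.08) higher. Of 20 extracellular matrix genes tested, 15 rose and 1 fell, with a median log2 change of 0.48 (camera adjusted p = 0.0066; adjusted p = 0.30 with an estimated correlation). That median was 0.22 with quantile normalization. FN1 (1.14 ± 0.05) and COL6A2 (1.12 ± 0.04) led. The largest limma adjusted p of the genes named was 9.3e-06. In limma, 9458 of 12548 genes passed, 6099 higher and 3359 lower, of which 681 were at least 2-fold higher and 13 at least 2-fold lower. Camera called 8 of 26 gene lists, 3 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 4638 higher and 4874 lower (490 and 42 at least 2-fold), and quantile normalization gave 3893 higher and 5281 lower (318 and 20 at least 2-fold). Leaving out mitochondrially encoded genes gave 7570 higher and 2248 lower (863 and 3 at least 2-fold), and removing the GC and length trend gave 6027 higher and 3071 lower (472 and 6 at least 2-fold). HSPA1A and HSPA1B are near-identical copies, so the division of reads between them is uncertain.

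HEK293T cells in the DRCC at 1 rpm expressed more NGFR (1.00 ± 0.177 to 39.3 ± 0.82 FPKM, log2 4.33 ± 0.06), INHBE (0.464 ± 0.0496 to 24.7 ± 0.819 FPKM, log2 4.14 ± 0.06) and TXNIP (15.7 ± 0.458 to 210.3 ± 2.61 FPKM, log2 3.66 ± 0.03), an arrestin that curbs glucose uptake, than in 2D. They expressed less POP1 (13.7 ± 0.342 to 2.53 ± 0.079 FPKM, log2 -2.06 ± 0.05), CA2 (157 ± 1.07 to 38.7 ± 1.39 FPKM, log2 -2.00 ± 0.03), a carbonic anhydrase, and MT1X (71.9 ± 4.08 to 17.6 ± 0.871 FPKM, log2 -1.97 ± 0.06), a metallothionein. The amino acid stress list was higher: 21 rose and 2 fell of 23 tested, and the median log2 change was 1.06 (camera adjusted p = 7.8e-05; adjusted p = 0.092 with an estimated correlation). The cystine transporter gene SLC7A11 (3.64 ± 0.09), ATF3 (3.23 ± 0.02) and ASNS (3.17 ± 0.06) led it. Of 21 cholesterol synthesis genes tested, 2 rose and 16 fell, with a median log2 change of -0.72 (camera adjusted p = 6.5e-06; adjusted p = 0.091 with an estimated correlation). NSDHL (-1.61 ± 0.05) fell most. Of 24 nuclear oxidative phosphorylation genes tested, 1 rose and 22 fell, with a median log2 change of -0.72 (camera adjusted p = 3.2e-09; adjusted p = 0.11 with an estimated correlation). That median was -0.44 with quantile normalization and -0.34 with the GC and length trend removed. UQCRFS1 (-1.35 ± 0.05) was first. Of 19 glycolysis genes tested, 4 rose and 14 fell, with a median log2 change of -0.64 (camera adjusted p = 5.8e-05; adjusted p = 0.19 with an estimated correlation). ENO2 (1.65 ± 0.05) rose while PGAM1 (-1.40 ± 0.03) and TPI1 (-1.30 ± 0.02) fell. Of 13 mitochondrially encoded genes tested, 1 rose and 10 fell, with a median log2 change of -1.09 (camera adjusted p = 7.6e-05; adjusted p = 0.11 with an estimated correlation). That median was -0.65 with quantile normalization. The share of fragments from these genes was 3.47 ± 0.0909%. Named genes had limma adjusted p of at most 5.7e-11. In limma, 10642 of 12548 genes passed, 6666 higher and 3976 lower, of which 1529 were at least 2-fold higher and 335 at least 2-fold lower. Camera called 9 of 26 gene lists, 0 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 5342 higher and 5264 lower (1077 and 671 at least 2-fold), and quantile normalization gave 4735 higher and 5556 lower (786 and 483 at least 2-fold). Leaving out mitochondrially encoded genes gave 7830 higher and 3010 lower (1947 and 174 at least 2-fold), and removing the GC and length trend gave 6512 higher and 3556 lower (1079 and 180 at least 2-fold).

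At 30 rpm, HEK293T cells had higher NGFR (1.00 ± 0.177 to 26.2 ± 0.45 FPKM, log2 3.77 ± 0.06), ANXA1 (1.43 ± 0.38 to 31.1 ± 2.13 FPKM, log2 3.73 ± 0.09) and ATF3 (12.7 ± 0.0607 to 179 ± 4.49 FPKM, log2 3.72 ± 0.02) than in 2D. HSPA1A (33.0 ± 4.89 to 4.91 ± 1.15 FPKM, log2 -2.53 ± 0.15) and MT1X (71.9 ± 4.08 to 11.8 ± 0.993 FPKM, log2 -2.51 ± 0.06) were among the lower genes. Amino acid stress genes were up: 21 rose and 2 fell of 23 tested, and the median log2 change was 0.80 (camera adjusted p = 1.1e-04; adjusted p = 0.096 with an estimated correlation). SLC7A11 (3.61 ± 0.09) and ASNS (3.59 ± 0.06) came after ATF3. Of 21 cholesterol synthesis genes tested, 2 rose and 16 fell, with a median log2 change of -0.73 (camera adjusted p = 3.8e-05; adjusted p = 0.096 with an estimated correlation). NSDHL (-1.67 ± 0.05) and LSS (-1.45 ± 0.04) were among those that fell. Of 19 glycolysis genes tested, 2 rose and 15 fell, with a median log2 change of -0.83 (camera adjusted p = 1.9e-05; adjusted p = 0.23 with an estimated correlation). PKM (-1.57 ± 0.02) and TPI1 (-1.50 ± 0.02) were first. Of 24 nuclear oxidative phosphorylation genes tested, 1 rose and 23 fell, with a median log2 change of -0.79 (camera adjusted p = 5.9e-08; adjusted p = 0.16 with an estimated correlation). That median was -0.49 with the GC and length trend removed. UQCRFS1 (-1.17 ± 0.05) and NDUFA1 (-1.03 ± 0.07) led. Of 13 mitochondrially encoded genes tested, 3 rose and 8 fell, with a median log2 change of -0.95 (camera adjusted p = 0.022; adjusted p = 0.33 with an estimated correlation). That median was -0.60 with quantile normalization. These genes took 4.23 ± 0.0903% of fragments. Limma adjusted p did not exceed 5.4e-09 among these genes. In limma, 10672 of 12548 genes passed, 6222 higher and 4450 lower, of which 1454 were at least 2-fold higher and 486 at least 2-fold lower. Camera called 7 of 26 gene lists, 0 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 5313 higher and 5349 lower (1169 and 791 at least 2-fold), and quantile normalization gave 4749 higher and 5598 lower (895 and 591 at least 2-fold). Leaving out mitochondrially encoded genes gave 7367 higher and 3440 lower (1871 and 268 at least 2-fold), and removing the GC and length trend gave 6052 higher and 4059 lower (1086 and 311 at least 2-fold).

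Relative to AggreWell, HEK293T cells at 1 rpm had more SLC7A11 (1.86 ± 0.0958 to 35.6 ± 3.99 FPKM, log2 3.67 ± 0.09), G0S2 (0.531 ± 0.144 to 17.4 ± 0.358 FPKM, log2 3.59 ± 0.10) and NGFR (2.60 ± 0.207 to 39.3 ± 0.82 FPKM, log2 3.48 ± 0.06). They had less GBE1 (29.5 ± 0.392 to 3.30 ± 0.158 FPKM, log2 -2.83 ± 0.05), the glycogen branching enzyme, TCEAL7 (20.2 ± 1.05 to 2.45 ± 0.272 FPKM, log2 -2.62 ± 0.07) and ALDOC (40.8 ± 0.612 to 6.30 ± 0.283 FPKM, log2 -2.52 ± 0.04). Hypoxia response genes were lower in the DRCC: 1 rose and 16 fell of 19 tested, and the median log2 change was -0.92 (camera adjusted p = 5.3e-07; adjusted p = 0.010 with an estimated correlation). BNIP3 (-2.16 ± 0.04), PFKFB4 (-2.09 ± 0.07) and LOX (-1.79 ± 0.07) fell most. Glycolysis genes followed: 1 rose and 18 fell of 19 tested, and the median log2 change was -1.22 (camera adjusted p = 1.2e-11; adjusted p = 0.0456 with an estimated correlation). PGK1 (-2.43 ± 0.03), SLC2A1 (-2.18 ± 0.03) and LDHA (-1.86 ± 0.02) came after ALDOC. Of 21 cholesterol synthesis genes tested, 1 rose and 19 fell, with a median log2 change of -0.98 (camera adjusted p = 4.6e-08; adjusted p = 0.014 with an estimated correlation). IDI1 (-1.65 ± 0.06) led. Amino acid stress genes rose: 19 rose and 2 fell of 23 tested, and the median log2 change was 0.84 (camera adjusted p = 2.0e-07; adjusted p = 0.014 with an estimated correlation). ASNS (2.86 ± 0.06) and CTH (1.73 ± 0.04) followed SLC7A11. Of 25 mitosis genes tested, 20 rose and 1 fell, with a median log2 change of 0.34 (camera adjusted p = 2.8e-04; adjusted p = 0.12 with an estimated correlation). CENPE (1.37 ± 0.09) and TTK (0.97 ± 0.09) rose most. Every gene named here had a limma adjusted p of 3.4e-07 or less. In limma, 9488 of 12548 genes passed, 5250 higher and 4238 lower, of which 251 were at least 2-fold higher and 190 at least 2-fold lower. Camera called 8 of 26 gene lists, 4 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 4697 higher and 4783 lower (208 and 219 at least 2-fold), and quantile normalization gave 4768 higher and 4737 lower (225 and 254 at least 2-fold).

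The 30 rpm spheroids of HEK293T, compared with AggreWell, had higher HMOX1 (36.0 ± 2.12 to 621 ± 1.97 FPKM, log2 4.07 ± 0.04), SLC7A11 (1.86 ± 0.0958 to 34.7 ± 0.858 FPKM, log2 3.64 ± 0.09) and the asparagine synthetase gene ASNS (1.28 ± 0.0178 to 21.1 ± 0.573 FPKM, log2 3.28 ± 0.06). GBE1 (29.5 ± 0.392 to 1.76 ± 0.23 FPKM, log2 -3.47 ± 0.05), SLC2A1 (67.8 ± 0.781 to 7.52 ± 0.352 FPKM, log2 -3.02 ± 0.03), a glucose transporter gene, and LOX (18.0 ± 0.837 to 1.94 ± 0.291 FPKM, log2 -2.70 ± 0.07) were lower. The hypoxia response list fell: 1 rose and 18 fell of 19 tested, and the median log2 change was -1.25 (camera adjusted p = 2.4e-07; adjusted p = 0.0074 with an estimated correlation). BNIP3 (-2.60 ± 0.04) and PFKFB4 (-2.34 ± 0.07) followed LOX. Of 19 glycolysis genes tested, 1 rose and 18 fell, with a median log2 change of -1.5 (camera adjusted p = 3.3e-10; adjusted p = 0.064 with an estimated correlation). PGK1 (-2.67 ± 0.03) and ALDOC (-2.45 ± 0.04) came after SLC2A1. Of 21 cholesterol synthesis genes tested, 0 rose and 19 fell, with a median log2 change of -1.01 (camera adjusted p = 5.4e-07; adjusted p = 0.019 with an estimated correlation). INSIG1 (-1.82 ± 0.04) and IDI1 (-1.79 ± 0.06) were among those that fell. Of 23 amino acid stress genes tested, 19 rose and 3 fell, with a median log2 change of 0.86 (camera adjusted p = 9.0e-07; adjusted p = 0.019 with an estimated correlation). ATF3 (1.92 ± 0.02) came after SLC7A11 and ASNS. Of 20 extracellular matrix genes tested, 1 rose and 18 fell, with a median log2 change of -0.46 (camera adjusted p = 5.4e-05; adjusted p = 0.16 with an estimated correlation). The collagen genes COL4A2 (-1.42 ± 0.03) and COL7A1 (-1.17 ± 0.06) led. The largest adjusted p in limma over these genes was 2.0e-09. In limma, 9856 of 12548 genes passed, 5001 higher and 4855 lower, of which 281 were at least 2-fold higher and 393 at least 2-fold lower. Camera called 8 of 26 gene lists, 3 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Removing the GC and length trend gave 4668 higher and 4690 lower (251 and 298 at least 2-fold), and testing without a filter gave 5637 higher and 6106 lower (283 and 396 at least 2-fold). A minimum mean FPKM of 5 gave 3221 higher and 3342 lower (185 and 256 at least 2-fold).

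Between the rotation speeds in HEK293T, SMIM11 (1.75 ± 0.47) was first among the higher genes, with 13.7, 1.10 and 6.26 FPKM in the 30 rpm libraries. Without the first of these its log2 fold change was 1.11 (limma adjusted p = 0.024), and it has a near-identical copy. After it came HMOX1 (273 ± 2.18 to 621 ± 1.97 FPKM, log2 1.18 ± 0.04) and ADAMTS1 (146 ± 2.15 to 318 ± 0.217 FPKM, log2 1.12 ± 0.02), a secreted protease. ANKRD37 (6.41 ± 0.778 to 2.04 ± 0.131 FPKM, log2 -1.28 ± 0.09), GDF15 (9.69 ± 0.994 to 3.55 ± 0.309 FPKM, log2 -1.23 ± 0.10) and INHBE (-1.22 ± 0.06) were lower at 30 rpm. Hypoxia response genes fell: 0 rose and 13 fell of 19 tested, and the median log2 change was -0.33 (camera adjusted p = 1.6e-04; adjusted p = 0.044 with an estimated correlation). LOX (-0.91 ± 0.07) and HILPDA (-0.76 ± 0.03) came after ANKRD37. Mitochondrially encoded genes rose: 11 rose and 0 fell of 13 tested, and the median log2 change was 0.28 (camera adjusted p = 9.7e-08; adjusted p = 0.044 with an estimated correlation). That median was 0.12 with quantile normalization. ND6 (0.41 ± 0.08) and ND1 (0.41 ± 0.04) were first. Of 20 extracellular matrix genes tested, 0 rose and 17 fell, with a median log2 change of -0.35 (camera adjusted p = 1.4e-05; adjusted p = 0.12 with an estimated correlation). COL4A2 (-0.56 ± 0.03) and COL18A1 (-0.54 ± 0.03) fell most. SMIM11 aside, limma adjusted p was at most 0.0012 for the genes named here. In limma, 6598 of 12548 genes passed, 2464 higher and 4134 lower, of which 3 were at least 2-fold higher and 13 at least 2-fold lower. Camera called 9 of 26 gene lists, 2 of them with an estimated correlation, and the counts above were the same adjusted over the list alone. Median-ratio scaling gave 3378 higher and 3127 lower (4 and 10 at least 2-fold), and quantile normalization gave 3361 higher and 3234 lower (5 and 9 at least 2-fold). Removing the GC and length trend gave 2551 higher and 4284 lower (2 and 8 at least 2-fold).

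**Figure D2:**
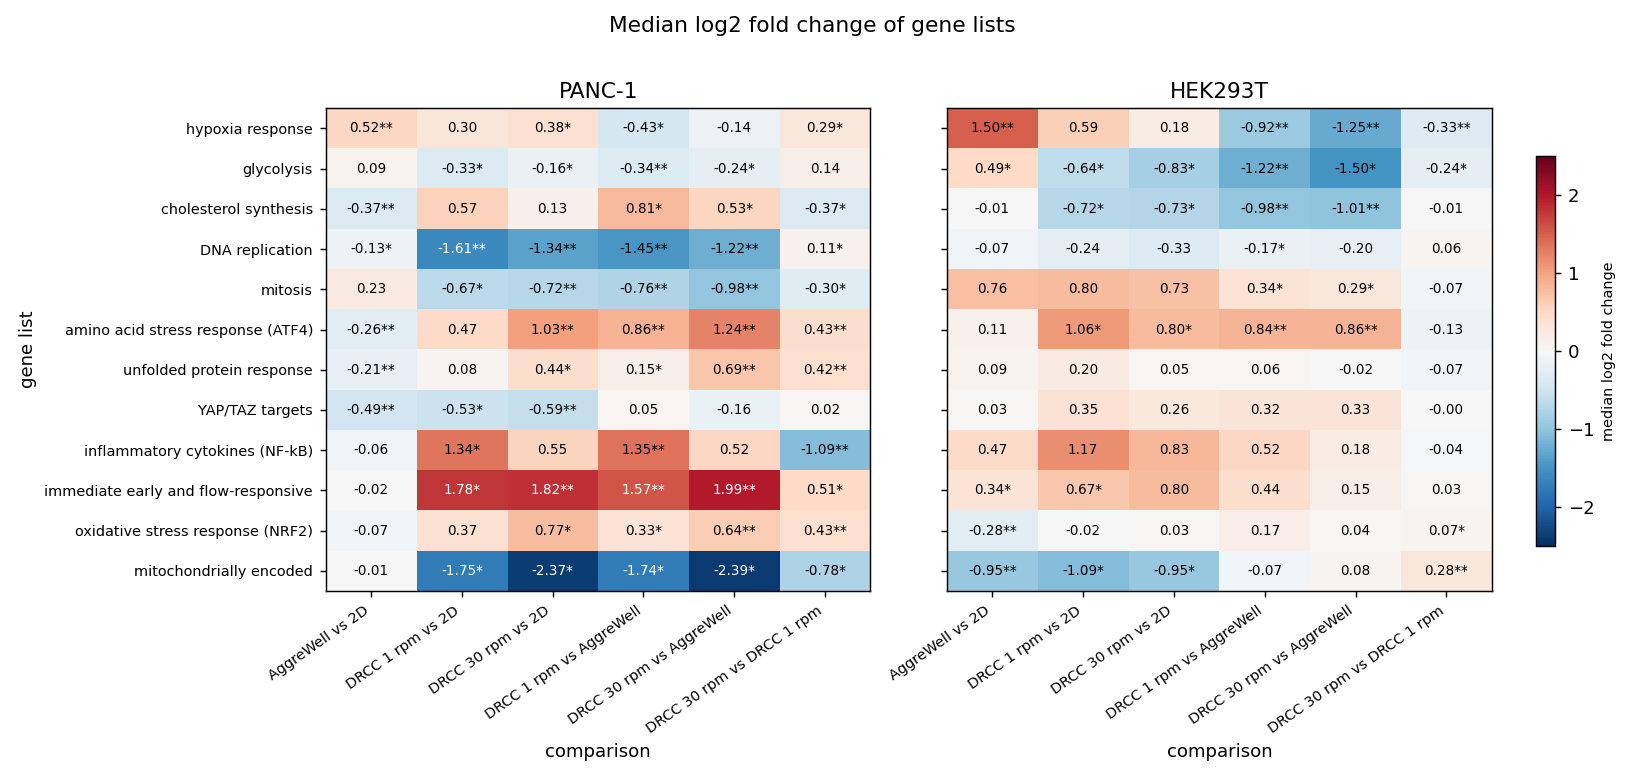
Median log2 fold change of 12 gene lists, down the side, in each of 6 comparisons of PANC-1 and HEK293T, printed in each cell and shown by colour (red for higher in the first-named format), with 1 asterisk for a camera adjusted p under 0.05 and a pair of asterisks where it also passed with an estimated correlation. DNA replication genes have their lowest medians in the PANC-1 DRCC columns against 2D and AggreWell, and HEK293T hypoxia response genes have a positive median for AggreWell against 2D and negative ones for DRCC against AggreWell.

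**Figure D3:**
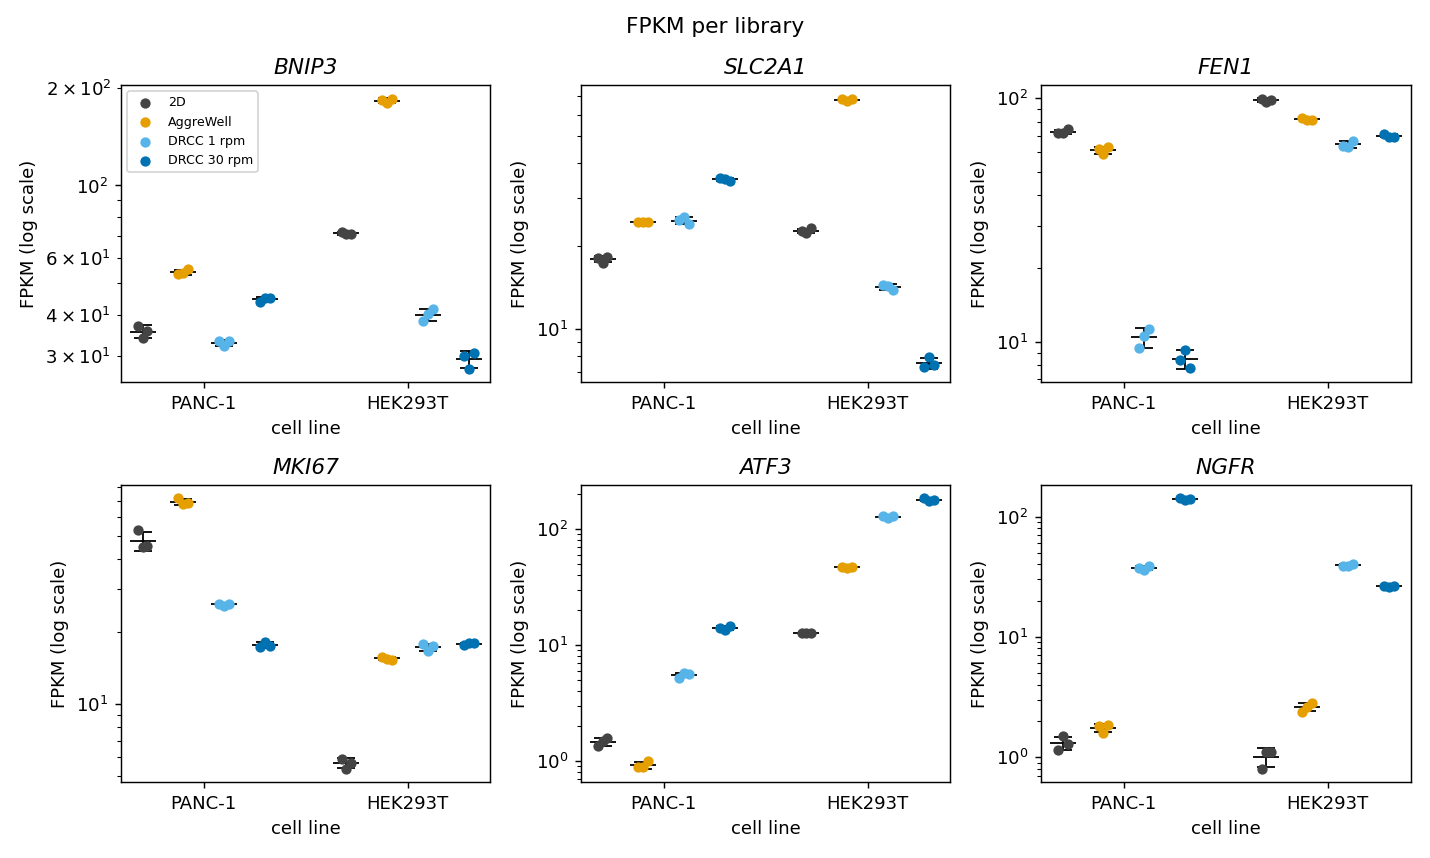
FPKM of 6 genes on a log axis, 1 point per library, with the mean and SD of each format as black bars (n = 3), for PANC-1 on the left and HEK293T on the right of each panel. BNIP3 and SLC2A1 are highest in the HEK293T AggreWell libraries, FEN1 is lowest in the PANC-1 DRCC libraries, and NGFR is higher in the DRCC libraries than in the other formats of both lines.

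The lines were then compared directly, as the PANC-1 log2 fold change less that of HEK293T. DNA replication genes were lower in PANC-1 relative to HEK293T for DRCC at 1 rpm against 2D (median difference -1.45, camera adjusted p = 3.5e-13; adjusted p = 1.4e-04 with an estimated correlation). The same held at 30 rpm (median difference -1.18, camera adjusted p = 3.9e-12; adjusted p = 2.3e-04 with an estimated correlation). Mitosis genes differed in the same direction at 30 rpm (median difference -1.19, camera adjusted p = 1.7e-11; adjusted p = 0.0048 with an estimated correlation). Hypoxia response genes rose less in PANC-1 AggreWell than in HEK293T AggreWell (median difference -0.73, camera adjusted p = 4.7e-09; adjusted p = 1.4e-04 with an estimated correlation). Cholesterol synthesis genes were higher in PANC-1 relative to HEK293T at 1 rpm against 2D (median difference 1.12, camera adjusted p = 8.2e-09; adjusted p = 0.0041 with an estimated correlation). YAP/TAZ targets were lower in that comparison (median difference -0.72, camera adjusted p = 1.4e-04; adjusted p = 0.0041 with an estimated correlation). Limma called a line difference for 7632 of 13392 genes for AggreWell against 2D, and for 10145 and 10642 genes for 1 and 30 rpm against 2D. Against AggreWell there were 9655 and 10288 such genes for 1 and 30 rpm, and 8461 differed between the speeds. Differences of at least 2-fold numbered 260, 1453, 2072, 988, 1570 and 326 in that order. Of the 13392 genes, 10752 were tested in both lines on their own, and the others are in these counts too. A gene hardly expressed in a line can hardly change there, so some of these differences need not be differing responses of shared genes.

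Fold changes of the 10752 genes tested in both lines were correlated across genes, which are not independent replicates, and the lines share no libraries. Pearson's r was 0.65 for AggreWell against 2D, 0.56 for 1 rpm and 0.44 for 30 rpm against 2D. It was 0.41 and 0.31 for 1 and 30 rpm against AggreWell, and -0.13 between the speeds. These r values were not corrected for GC content. Spearman correlations of fold change with GC were alike for AggreWell against 2D, -0.23 in PANC-1 and -0.26 in HEK293T. They had opposite signs for 30 rpm against 2D (0.14 and -0.38), against AggreWell (0.31 and -0.32) and against 1 rpm (0.37 and -0.11). The signs also differed for 1 rpm against AggreWell (0.11 and -0.31). For 1 rpm against 2D the values were -0.036 and -0.37. How far such trends set r was not tested.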

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

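The tests of poly(A) selection, of library scaling for AggreWell alone and of low depth by the 2 formats compared were chosen only after the result was seen. So were the removal of GC and length trends, the set of histone genes and the directions of single genes under other scalings. The first part gives genes that were called in opposite directions in the 2 lines and whose difference between the lines passed limma's interaction test, with adjusted p of at most 6.5e-16. Values are log2 fold changes in PANC-1 and then in HEK293T, followed by their difference ± SE over 24 libraries. For AggreWell against 2D, they were JUN (-0.46 and 1.56, difference -2.02 ± 0.04), TNFRSF12A (-0.86 and 1.18, difference -2.03 ± 0.05) and CAVIN1 (-0.82 and 0.56, difference -1.37 ± 0.04). The others were UAP1 (-0.42 and 0.83, difference -1.25 ± 0.04), INSIG1 (-0.96 and 1.11, difference -2.07 ± 0.06) and ARRB1 (1.37 and -0.14, difference 1.51 ± 0.05). For 1 rpm against 2D, they were SCD (1.47 and -1.43, difference 2.90 ± 0.03), TNFRSF12A (-1.17 and 1.94, difference -3.10 ± 0.05) and FASN (1.46 and -1.15, difference 2.61 ± 0.04). With them came ANLN (-0.76 and 1.65, difference -2.41 ± 0.04), RRM2 (-1.85 and 0.08, difference -1.93 ± 0.03) and PIM3 (2.33 and -0.28, difference 2.61 ± 0.05). For 30 rpm against 2D, they were SCD (0.74 and -1.41, difference 2.15 ± 0.03), HSPA1B (1.88 and -2.06, difference 3.94 ± 0.05) and ANLN (-1.0 and 1.68, difference -2.67 ± 0.04). Next were CCDC85B (2.16 and -1.07, difference 3.22 ± 0.05), DDX3X (-0.78 and 1.55, difference -2.33 ± 0.04) and ATAD2 (-0.73 and 2.26, difference -2.99 ± 0.05). For 1 rpm against AggreWell, they were SCD (1.54 and -1.80, difference 3.34 ± 0.03), FASN (1.66 and -1.03, difference 2.70 ± 0.04) and MSMO1 (2.20 and -1.16, difference 3.36 ± 0.05). Then followed FDFT1 (1.49 and -1.07, difference 2.57 ± 0.04), RRM2 (-1.78 and 0.26, difference -2.04 ± 0.03) and PIM3 (2.36 and -0.30, difference 2.66 ± 0.05). For 30 rpm against AggreWell, they were SCD (0.81 and -1.78, difference 2.59 ± 0.03), SLC2A1 (0.50 and -3.02, difference 3.51 ± 0.04) and ND6 (-7.86 and 0.49, difference -8.34 ± 0.13). After these stood BHLHE40 (2.19 and -0.85, difference 3.04 ± 0.05), PIM3 (2.70 and -0.13, difference 2.83 ± 0.05) and RACGAP1 (-1.17 and 0.58, difference -1.75 ± 0.03). For 30 rpm against 1 rpm, they included HSPA1B (2.13 and -0.84, difference 2.97 ± 0.05), PSAT1 (1.22 and -0.39, difference 1.61 ± 0.04) and ND6 (-5.13 and 0.41, difference -5.55 ± 0.13). Another was TNFRSF12A (1.28 and -0.57, difference 1.85 ± 0.05). SCD, FASN, MSMO1 and FDFT1 belong to lipid and sterol synthesis, and ANLN, RRM2 and RACGAP1 to the cell cycle. HSPA1B and ND6 are uncertain because of close copies. For 3 genes the opposite directions depended on the processing. For 1 rpm against 2D, RRM2 changed by -2.03 in PANC-1 and -0.13 in HEK293T with median-ratio scaling, so RRM2 fell in both lines there. The HEK293T value of PIM3 for 30 rpm against AggreWell was 0.065 (limma adjusted p = 0.058) with the GC and length trend removed, -0.042 (limma adjusted p = 0.31) with quantile normalization and -0.084 (limma adjusted p = 0.0542) with mitochondrially encoded genes left out. For 1 rpm against 2D it was -0.050 (limma adjusted p = 0.22) with quantile normalization, and that of ARRB1 for AggreWell against 2D was -0.031 (limma adjusted p = 0.54) with mitochondrially encoded genes left out.

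Hypoxia response genes rose in HEK293T AggreWell, with a median 1.38 above that of all genes on the log2 scale (bootstrap SE 0.153, 19 genes). A trend with GC content or transcript length was considered, since fold changes there correlated with length (Spearman 0.31 across genes). With that trend removed the median was 1.5592 above all genes, so the trend does not account for the whole rise. With median-ratio scaling it was 1.36, but scaling moves the list and all genes nearly alike, so this value cannot decide on scaling. That scaling moved the median of all genes from 0.116 to -0.014, which is far less than the rise. The culture format stays open as a biological explanation, which was not tested.

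Calls of at least 2-fold were mostly higher in the 3D formats than in 2D. With the GC and length trend removed, the lowest share of higher calls over the 6 comparisons was 75.2%, which argues against that trend. With a mean FPKM of at least 5 over all libraries of a line the lowest was 64.8%, but 9 of those 12 are 3D, which favours genes higher in 3D; over the 2 formats compared it was 63.7% ± 1.52 (binomial SE, genes taken as independent), narrowly over the bound of 60% set for low depth as the cause. With median-ratio scaling the share was 92.1% ± 1.17 for AggreWell in HEK293T, which argues against scaling there, and 67.2% ± 4.10 in PANC-1. For 1 and 30 rpm it was 56.6% ± 1.25 and 59.2% ± 1.27 in PANC-1 and 61.6% ± 1.16 and 59.6% ± 1.11 in HEK293T, so in these 5 comparisons, none over 60% by 2 SE, scaling and a real excess of higher genes cannot be told apart. The culture format as the source of the excess was not tested apart from these and stays open.

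ND6 and other mitochondrially encoded transcripts were lower in PANC-1 at 30 rpm than in 2D, and unevenly so: the log2 change was -7.48 for ND6, -0.87 for ND5 and -0.13 for ND4. Stronger poly(A) selection would lower replication-dependent histone mRNAs, which lack a poly(A) tail, along with ND6. The median of 26 such histone genes was 1.98 (bootstrap SE 0.428). Histone genes rose here although DNA replication genes fell, which is itself unexplained, and their close copies make their levels uncertain. Their rise therefore cannot decide on poly(A) selection. A change in strand handling would lower antisense genes, but 210 of them had a median 0.186 above all genes, so they did not fall as a group. Reads of antisense genes and their overlapping partners could not be told apart, so this does not exclude strand handling. With median-ratio scaling the mitochondrial median was -2.57, so scaling does not account for the fall. A difference in poly(A) selection stays open for ND6. For the other mitochondrially encoded transcripts, such as COX3 (-3.42), no such prediction was made and poly(A) selection was not tested. Reads lost to nuclear copies and a change in mitochondrial transcripts with rotation also stay open, and neither of these was tested. The fall was not particular to 30 rpm: ND6 read 113 to 126 FPKM at 1 rpm, against 564 to 707 in 2D.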

How the results depend on the processing

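The use of voom on recovered fragments and the removal of GC and length trends were chosen after seeing the data, and the other alternatives before. Counts follow the order AggreWell, 1 rpm and 30 rpm against 2D, 1 rpm and 30 rpm against AggreWell, and 30 rpm against 1 rpm. Counts of at least 2-fold changes moved most. With a pseudocount of 0.1, which by construction widens the fold changes of low genes, they were 549, 2678, 2609, 1690, 1935 and 305 in PANC-1, 1499, 2915, 3031, 977, 1337 and 113 in HEK293T, and 764, 2670, 3495, 1989, 2734 and 908 for the line difference. With voom they were 699, 2825, 2749, 1798, 2063 and 356 in PANC-1, 1656, 3090, 3202, 1080, 1455 and 153 in HEK293T, and 858, 2874, 3693, 2190, 2935 and 1083 for the line difference. Limited to a mean FPKM of at least 5, which tests fewer genes, they were 111, 1024, 1002, 595, 752 and 76 in PANC-1, 474, 1235, 1362, 280, 441 and 9 in HEK293T, and 133, 917, 1347, 594, 949 and 204 for the line difference, and calls of any size were 5464, 6569, 6519, 6294, 6381 and 5506 in PANC-1, 6346, 7049, 7104, 6333, 6563 and 4601 in HEK293T, and 4919, 6463, 6683, 6135, 6435 and 5590 for the line difference. Quantile normalization moved AggreWell against 2D to 101 genes in PANC-1 and 338 in HEK293T. With GC and length trends removed, counts moved to 105 for AggreWell against 2D in PANC-1, 10 between the speeds in HEK293T, and 1325, 964 and 194 for the line differences of 30 rpm against 2D, AggreWell and 1 rpm. The cause was not tested for these. Voom does not add the pseudocount of 1 FPKM, which narrows the fold changes of low genes. How far that set the voom counts was not tested. Gene list calls numbered 210 of 480, and 97 with an estimated correlation. Totals of called genes and of 2-fold changes moved by less than 1.5 times with any library left out, with no filter, with median-ratio scaling, with mitochondrially encoded genes left out, with the 2 formats fitted alone, or with robust shrinkage. Counts by direction moved further with scaling and with mitochondrially encoded genes left out, a setting that also scaled libraries to a common FPKM total. For AggreWell against 2D in HEK293T, 13 genes at least 2-fold lower became 42 with median-ratio scaling and 3 with those genes left out. Such counts stand beside each comparison within a line. Refits of named genes numbered 4083, of which 4078 kept their direction and call; BOLA2B lost its call between the speeds in PANC-1 with no filter, the formats fitted alone, robust shrinkage, and either of replicates 1 and 2 at 1 rpm left out. Its adjusted p there ran from 0.061 to 0.10. Fold changes correlated with GC content across genes, from Spearman -0.38 to 0.37 over the 12 comparisons, and with length from -0.39 to 0.31.

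The labels do not say that a replicate number marks a shared batch, and not every same-numbered pair of libraries correlated over 0.1, so the samples were not treated as paired. Deviations of same-numbered libraries correlated at -0.023 on average in PANC-1, with 1 of 18 pairs over 0.1, and at 0.092 in HEK293T, with 6 of 18, the highest at 0.43. Libraries that correlated best with their own number in the other formats were 1 of 12 in PANC-1 and 8 of 12 in HEK293T. A batch shared by replicate number is therefore not excluded in HEK293T. With the replicate block, calls were 8032, 9977, 9927, 9494, 9604 and 7831 in PANC-1 and 9584, 10758, 10780, 9651, 10004 and 6901 in HEK293T, and 208 gene lists were called, 207 of them among the 210 called without it. The block raised calls in all 6 HEK293T comparisons and lowered them in all 6 of PANC-1, none by over 1.5 times.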

Other observations

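The regroupings for the line difference were redrawn after a first draw with repeats had been seen, and the shared 2-fold changes were counted after each line's own counts were known. p53 target genes were higher in PANC-1 at 30 rpm than in 2D. Of 19 p53 targets tested, 17 rose and 1 fell, with a median log2 change of 0.61 (camera adjusted p = 0.0047; adjusted p = 0.13 with an estimated correlation). That median was 0.37 with quantile normalization. The largest rises were those of GDF15 (2.52 ± 0.03), BBC3 (2.15 ± 0.08) and BTG2 (1.29 ± 0.08). Metallothionein genes were lower: 0 rose and 5 fell of 5 tested, and the median log2 change was -0.93 (camera adjusted p = 0.015; adjusted p = 0.14 with an estimated correlation). MT1E (-1.36 ± 0.10) and MT1A (-1.08 ± 0.10) fell most. The unfolded protein response was higher: 14 rose and 1 fell of 17 tested, and the median log2 change was 0.44 (camera adjusted p = 0.019; adjusted p = 0.075 with an estimated correlation). That median was 0.24 with median-ratio scaling. DNAJB9 (2.10 ± 0.08) and HERPUD1 (2.03 ± 0.05) led it. Between the speeds, cholesterol synthesis genes were lower at 30 rpm in PANC-1. Of 21 such genes tested, 3 rose and 18 fell, with a median log2 change of -0.37 (camera adjusted p = 8.1e-06; adjusted p = 0.0503 with an estimated correlation). HMGCS1 (-1.19 ± 0.04) fell most. In HEK293T, epithelial markers differed between the speeds. Of 11 epithelial markers tested, 0 rose and 8 fell, with a median log2 change of -0.32 (camera adjusted p = 0.0076; adjusted p = 0.19 with an estimated correlation). KRT8 (-0.71 ± 0.05) and CLDN4 (-0.65 ± 0.10) were lower at 30 rpm. All genes named here were called by limma, and counts adjusted over the list alone were the same.

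Across the 10752 genes tested in both lines, 91 were at least 2-fold higher in both for AggreWell against 2D, where independent lists would share 6.57, and 0 were lower in both. For 1 rpm against 2D there were 451, against 139, and 73 were lower in both, against 11.3. For 30 rpm against 2D there were 363 higher in both, against 141, and 70 lower in both, against 13.4. Genes changed at least 2-fold in opposite directions numbered 1, 14 and 21 in these comparisons. Trends with GC content or length were not removed for these counts.

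Libraries were also regrouped to see how often other groupings gave as many calls. Within a line, 3 libraries against 3 give 10 groupings, too few for a share under 0.05. In all 12 comparisons 1 of 10 groupings, the real one, gave as many called genes and as many 2-fold changes, and the highest other count was 0, against the real counts given in the report. Every other grouping mixes the 2 formats and puts their difference into the residual spread. The 0 thus follows from the construction and says nothing about chance. Gene lists did otherwise. In the order of the comparisons above, 2, 5, 1, 1, 1 and 1 of 10 groupings in PANC-1 gave as many lists as the real 14, 10, 15, 16, 11 and 12, and the highest others were 14, 11, 12, 14, 10 and 10. In HEK293T the numbers were 4, 3, 1, 4, 4 and 1, against real counts of 8, 9, 7, 8, 8 and 9 and highest others of 8, 11, 6, 9, 9 and 6. The mixed groupings keep part of the difference between formats, and camera tests each list against the other genes. These list counts therefore say nothing about chance either.

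For the line difference, 100 groupings were counted. As many called genes came from 3, 2, 2, 1, 2 and 1 of them, with highest others of 7884, 11705, 11585, 7399, 10911 and 7816. As many 2-fold changes came from 6, 15, 7, 4, 2 and 1, with highest others of 1044, 4922, 4692, 1338, 2814 and 204. As many lists came from 1, 2, 7, 1, 49 and 3, with highest others of 18, 15, 15, 13, 15 and 12. The real counts are 7632, 10145, 10642, 9655, 10288 and 8461 genes, 260, 1453, 2072, 988, 1570 and 326 2-fold changes and 19, 15, 12, 14, 11 and 12 lists. Other groupings with as many called genes or 2-fold changes all left the real groups of 1 line whole, so they hold that line's own difference. Groupings that mixed both lines put the difference between formats into the residual spread and gave at most 1 called gene. By this construction the shares say nothing about chance in a difference between the lines.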
